A study of Homo sapiens with 6 samples.

How the data were processed

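ERα ChIP-seq was performed in MCF-7 and T47D cells transduced with lentivirus and selected with puromycin, using an antibody against ERα, per the labels' protocols. Each line had 1 control sample with a non-targeting guide RNA pool and 2 samples with guides against enh588. The data were 2 peak lists, 1 for each cell line. The name of each deposited list carries 1 sample code, 1 index and 1 sequencing lane, and says that the list is an intersection, without saying of what. The code holds the letters c_m for MCF-7 and c_t for T47D, which are not explained. Which libraries each list was called on, whether libraries were pooled, and what filtering followed peak calling are not given in the sources used here.

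The build hg19 and the tools BWA 0.7.5 and MACS are named, with no role or order, per the submitters' processing notes, and no version of MACS is given. The deposited lists give for each peak a chromosome, start, end, name and score, and the names start with a MACS label. The scale of the deposited score is not given in the sources used here. Every score was at least 50, and the commonest was exactly 3100. Scores were therefore used to describe and rank peaks within a list. Where scores of both lists are given together, their sizes were not compared between lists. Peak numbers in the names ran to 27158 in MCF-7 and 6857 in T47D, so that 138 numbers (0.508%) and 155 numbers (2.26%) were absent. The step that left them out is not given in the sources used here. If a peak caller had fewer reads or a weaker enrichment in one line, that line's list would be shorter with narrower peaks, so the number, width and overlap of peaks all depend on depth, which is unknown here.

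Starts were converted to positions counted from 1. No peaks overlapped within a list. A peak was called shared when it overlapped a peak of the other list by at least 1 bp. Shares are given with exact Clopper-Pearson intervals at 95%, which treat peaks as independent and cover counting error only. Chance overlap was measured from 100 random placements of the T47D peaks within their chromosomes, over the span of the peaks of both lists. Peaks were ranked by score in 5 classes of equal size. The genome was divided into bins of 5 Mb, and for bins with at least 20 peaks the MCF-7 part of all peaks was compared with the genome-wide part of 80.1%. The number of bins that counting alone places outside was summed from the binomial distribution at each bin's number of peaks. No p-values were computed, since there was 1 list per cell line.

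Annotation of peaks, response element motifs and counts over fixed gene lists had been planned for the case that an hg19 genome or annotation was at hand. The reference used here was a gene table of GRCh38.p14, so these were not run. Its coordinates were not used. It served for gene names and gene order, and 7 of 7 named symbols were found on the stated chromosome. The planned window of 500 kb around the CCND1 start site was replaced by the megabase that holds the gene. The windows for CCND1, ESR1, GREB1, TFF1, PGR, GATA3 and FOXA1, and the places of centromeres and chromosome bands, were taken from general knowledge of hg19 to whole megabases and were not checked against an hg19 annotation. The window was 1 Mb for each gene except PGR, for which it was 2 Mb. A centromere gap was the stretch without peaks in either list around the centromere, and peaks within 2 Mb of it were called near.

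The rule for what is named was set before the data were examined. It named those 7 genes, the 5 peaks of highest score in each list, and the strongest peak near CCND1. It also named the 5 bins with the highest and the 5 with the lowest MCF-7 part whose interval excluded the genome-wide part. The parts of the rule that needed gene distances could not be applied, and the strongest peak of the CCND1 megabase stands in for the strongest peak within a set distance of the gene. TRPS1, ZNF217 and the single megabases in the closing section were chosen after the data were seen.

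Alternatives were other definitions of overlap (at least 50% of the shorter peak, midpoints within 200 bp, peaks resized to 400 bp), the stronger 50% of each list, MCF-7 peaks matched to T47D in number, merging of peaks within 500 bp, ranking by width, and other bin sizes. Leaving out peaks near centromere gaps was added after the data were seen. The overlap and bin steps were tested on simulated lists. All 3351 planted overlaps were recovered, as were 23 of 30 bins with a planted 4-fold loss of T47D peaks. Of 481 unchanged bins, 4 were called. No gain of T47D peaks was planted, so the recovery of bins with a low MCF-7 part was not checked. The planted peaks were centred on MCF-7 peaks, so their recovery checks the computation only. The simulated T47D peaks in the bin test were drawn from MCF-7 positions, so that its bins scattered less than independent counts would. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9.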

Results

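Binding of oestrogen receptor alpha (ERα), the ligand-activated transcription factor encoded by ESR1, was measured by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in MCF-7 and T47D cells. Both are established human breast cancer cell lines that express ERα. Each line was represented by 3 samples, 1 transduced with a non-targeting guide RNA pool and 2 with guides against an enhancer named enh588. The data used here were 1 peak list per cell line, and the labels of all 3 samples of a line pointed to the same list. The lists carried no value per sample, so ERα binding in enh588-targeted cells could not be set against binding in control cells, and that comparison was not made. The comparison reported is between the MCF-7 list and the T47D list. There were no replicate lists, no test between the lines was possible, and the read depth behind each list is unknown. Intervals are exact 95% Clopper-Pearson intervals over peaks and cover counting error only.

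The MCF-7 list held 27020 ERα peaks and the T47D list 6702, a ratio of 4.03. MCF-7 peaks had a median width of 500 bp (quartiles 450 and 550 bp) and covered 13841.5 kb. T47D peaks had a median width of 350 bp (quartiles 300 and 400 bp) and covered 2338.39 kb, so that covered length differed 5.92-fold. Peak scores were the authors' own and their scale is not stated. The median score was 135 in MCF-7 and 122 in T47D, and the lowest scores were 50 and 50.02. Without replicates or depth, the difference in peak number describes these 2 lists and not the cell lines in general.

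Most T47D peaks were found among those of MCF-7, and most MCF-7 peaks had no T47D counterpart. Of the T47D peaks, 3992 of 6702 overlapped an MCF-7 peak by at least 1 bp (59.6%, interval 58.4 to 60.7%). Of the MCF-7 peaks, 3991 of 27020 overlapped a T47D peak (14.8%, interval 14.3 to 15.2%). When T47D peaks were placed at random within their chromosomes, a mean of 0.826% overlapped an MCF-7 peak, with a range of 0.567 to 1.13% over 100 placements. The observed share was 72.1 times that mean. The placements were uniform over each chromosome's span, centromere gaps included, and took no account of mappability or open chromatin. The multiple is therefore over uniform placement only. With MCF-7 peaks drawn at random to match T47D in number, 14.7% of either list was shared. Both values follow from the draw. Random drawing leaves the expected MCF-7 share at its 14.8%, and with overlap nearly 1 to 1 the T47D share must come to about the same. They show only that the T47D share depends on the length of the MCF-7 list. When the strongest MCF-7 peaks were taken in that number, 32.7% of either list was shared, a change in strength as well as in number.

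In both lists the shared part was higher in classes of higher score. Shared MCF-7 peaks had a median score of 389 and the other MCF-7 peaks 120. In T47D the corresponding medians were 154 and 94.1. Each list was divided by score into 5 classes of equal size. In MCF-7, 35.8% of the strongest class (interval 34.5 to 37.1%) and 4.79% of the weakest class (interval 4.24 to 5.40%) overlapped a T47D peak. In T47D, 75.9% of the strongest class (interval 73.5 to 78.2%) and 46.5% of the weakest class (interval 43.8 to 49.2%) overlapped an MCF-7 peak. The strongest class held 1935 of the 3991 shared MCF-7 peaks and 1017 of the 3992 shared T47D peaks. When T47D peaks were ranked by width, the shared part was 65.4% in the first class and 68.4% in the second, with overlapping intervals. Among the 500 strongest peaks, 324 of the MCF-7 peaks (64.8%, interval 60.4 to 68.99%) and 396 of the T47D peaks (79.2%, interval 75.4 to 82.7%) were shared. Across the 3991 shared MCF-7 peaks and their strongest T47D partners, Spearman's rho of the scores was 0.394. This correlation is across peaks, which are not independent replicates.

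**Figure D1:**
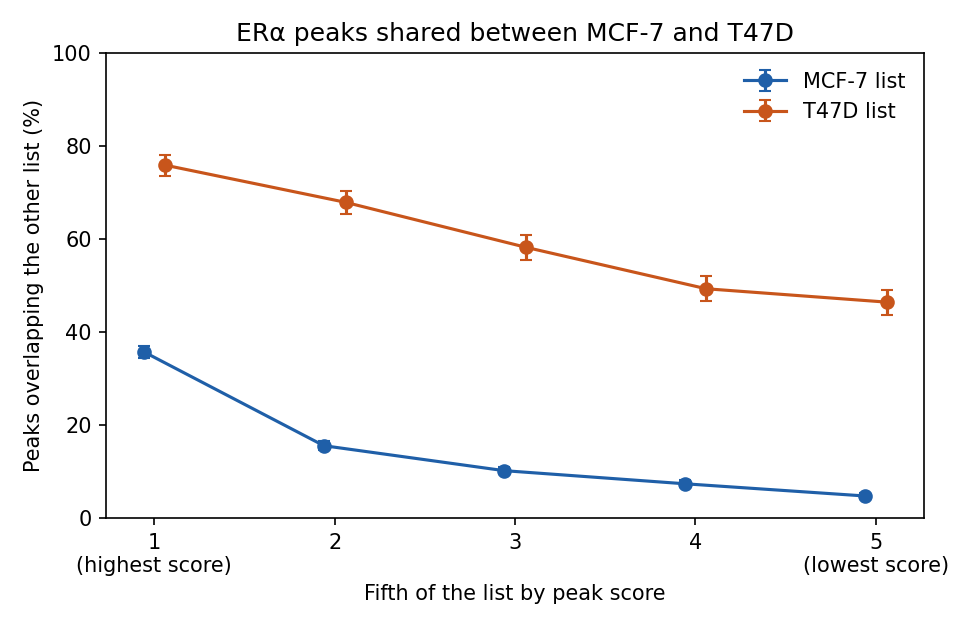
Percent of ERα peaks that overlapped a peak of the other cell line's list (vertical axis), for 5 score classes of equal size from strongest to weakest (horizontal axis). Points are the MCF-7 and T47D lists and bars are exact 95% intervals over peaks, and the share fell from 35.8 to 4.79% in MCF-7 and from 75.9 to 46.5% in T47D.

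The 5 MCF-7 peaks with the highest scores had no T47D partner, although 17 of the 30 MCF-7 peaks that scored above 3100 had one (56.7%, interval 37.4 to 74.5%). In hg19 coordinates they lay at chromosome 5, 132585000 to 132585649 (score 3233), chromosome 17, 13679227 to 13679926 (score 3225), chromosome 9, 80211676 to 80212325 (score 3218), chromosome 14, 34250443 to 34251092 (score 3216), and chromosome 21, 16545343 to 16545992 (score 3213). Of the 5 T47D peaks with the highest scores, 4 had an MCF-7 partner, as did 9 of the 11 above 3100 (81.8%, interval 48.2 to 97.7%). The highest, at chromosome 6, 12416388 to 12416837 (score 3210), overlapped an MCF-7 peak of score 209. The peak at chromosome 1, 88180601 to 88181200 (score 3190) had none. The peaks at chromosome 6, 21738738 to 21739387 (score 3189), chromosome 3, 188816738 to 188817237 (score 3185), and chromosome 3, 50642488 to 50643187 (score 3182) overlapped MCF-7 peaks of score 3100, 2070 and 2215. A score of exactly 3100 was carried by 162 MCF-7 and 82 T47D peaks, so the order among the highest scores is poorly resolved. The scale of the score is not given, so the peaks above 3100 cannot be taken as stronger than those tied at 3100, and they may be weaker. The 5 named peaks of each list are therefore those of highest score, which need not be the strongest. Of the peaks tied at that score, 66.7% were shared in MCF-7 (interval 58.8 to 73.9%) and 72.0% in T47D (interval 60.9 to 81.3%).

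CCND1 encodes cyclin D1, which drives entry into the cell cycle, and enh588 is known as an ERα-bound enhancer of this gene. The position of the element is not given in the sources used here, and no peak is assigned to it. The megabase of chromosome 11 from 69 to 70 Mb, which holds CCND1, contained 42 MCF-7 and 10 T47D peaks. Of 2691 megabase windows with a peak, 99.6% had fewer MCF-7 peaks and 95.4% had fewer T47D peaks. In this window, 9 MCF-7 and 9 T47D peaks were shared. The strongest peak of the window was the same site in both lines, at 69329943 to 69330592 with a score of 3021 in MCF-7 and at 69330102 to 69330501 with a score of 1031 in T47D. Within their own lists these scores stood at percentiles 99.2 and 92.4. MCF-7 peaks made up 80.8% of the peaks there (interval 67.5 to 90.4%), against 80.1% over the whole genome. In the gene order of GRCh38.p14, the nearest protein-coding genes are TPCN2, SMIM38 and MYEOV on one side of CCND1. On the other side, past 1 gene without an assigned name, they are LTO1, FGF19, FGF4 and FGF3.

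**Figure D2:**
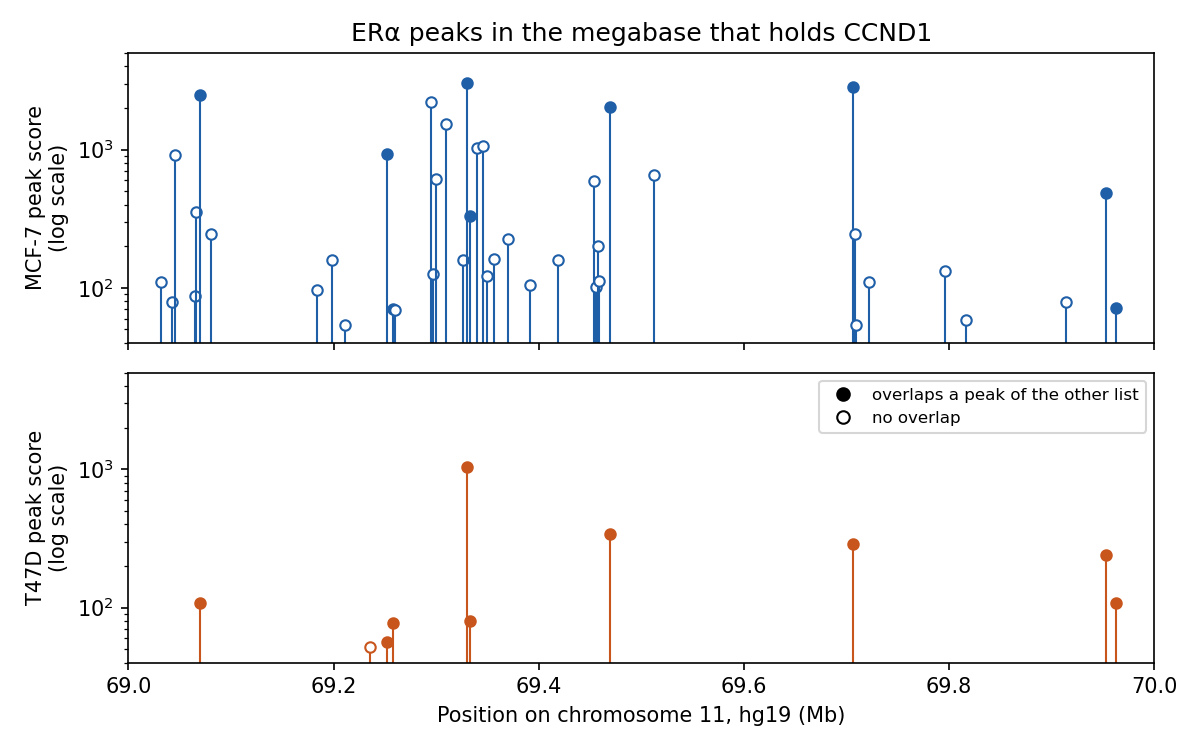
ERα peaks of MCF-7 (upper panel) and T47D (lower panel) by hg19 position on chromosome 11 in Mb, with the deposited peak score on a log axis. Filled points overlap a peak of the other list and open points do not, and the highest point of both panels is the shared site of score 3021 in MCF-7 and 1031 in T47D.

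The windows that hold PGR, GREB1 and FOXA1 were richer in T47D peaks, relative to MCF-7 peaks, than the genome as a whole. The window of 2 Mb that holds PGR, the progesterone receptor gene and a classical ERα target, had 31 MCF-7 and 26 T47D peaks. The MCF-7 part was therefore 54.4% (interval 40.7 to 67.6%), and 99.2% of windows of that size had fewer T47D peaks. Its highest-scoring MCF-7 peak, at chromosome 11, 101206793 to 101207442 (score 3165), overlapped a T47D peak of score 3100. The megabase of GREB1, an oestrogen-induced gene whose product binds ERα, had 32 and 18 peaks, an MCF-7 part of 64.0% (interval 49.2 to 77.1%). The megabase of FOXA1, the pioneer factor that opens chromatin for ERα, had 16 and 11 peaks, a part of 59.3% (interval 38.8 to 77.6%). Its highest-scoring peak was again the same site in both lines, at chromosome 14, 38015943 to 38016592 in MCF-7. The scores were 1919 in MCF-7 (percentile 97.4 of its list) and 3150 in T47D (percentile 99.9).

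In the other windows the interval of the MCF-7 part included the genome-wide 80.1%. The megabase of TFF1, which encodes a secreted trefoil peptide induced by oestrogen, had 50 MCF-7 and 9 T47D peaks, and 3 windows of the genome had more MCF-7 peaks. The megabase of GATA3, a luminal transcription factor gene, had 37 and 11 peaks. The megabase chosen for ESR1 itself had 15 and 2 peaks, and both T47D peaks were shared. Peaks were counted per window and were not assigned to genes, since no hg19 annotation was used.

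**Figure D3:**
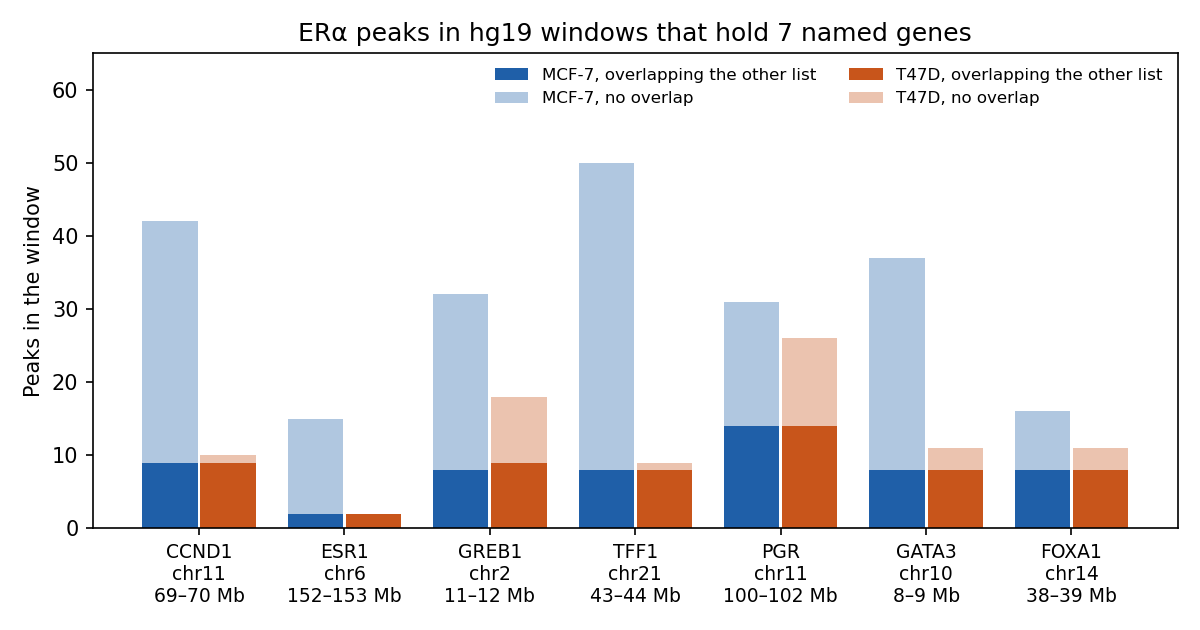
Number of ERα peaks (vertical axis) in hg19 windows that hold 7 named genes, with MCF-7 and T47D side by side. Dark parts are peaks that overlap the other list and light parts are peaks that do not. MCF-7 peaks range from 15 for ESR1 to 50 for TFF1, and T47D peaks from 2 for ESR1 to 26 for PGR. The PGR window is 2 Mb and each of the others 1 Mb.

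Of 528 bins of 5 Mb with at least 20 peaks over both lists, 74 had an MCF-7 part whose interval lay above 80.1% and 61 had one whose interval lay below, where binomial counting at these bin sizes would place 17.5 outside on average. Bins with MCF-7 peaks and no T47D peak were led by chromosome 16, 60 to 65 Mb, with 33 MCF-7 peaks. The next were chromosome 11, 20 to 25 Mb (23 peaks), chromosome 4, 175 to 180 Mb (22 peaks), chromosome X, 95 to 100 Mb (22 peaks), and chromosome 6, 100 to 105 Mb (20 peaks). The bins with the lowest MCF-7 part were chromosome 21, 5 to 10 Mb, with 1 MCF-7 and 39 T47D peaks, chromosome 9, 65 to 70 Mb, with 3 and 44, and chromosome 21, 10 to 15 Mb, with 3 and 38. They were followed by chromosome 7, 60 to 65 Mb, with 5 and 45, and chromosome 2, 90 to 95 Mb, with 3 and 17. All of these low bins lay beside a centromere gap, as did 17 of the 61 bins below the genome-wide part and 37 of all 528. As shares of the bins tested, 14.02% lay above and 11.6% below. With bins of 10 Mb, 48 of 304 (15.8%) lay above and 47 (15.5%) below, and with bins of 2 Mb, 70 of 736 (9.51%) lay on each side. With the strongest MCF-7 peaks matched to T47D in number, 41 of 306 (13.4%) lay above a genome-wide part of 50% and 32 (10.5%) below it.

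T47D peaks within 2 Mb of a centromere gap were seldom shared. They numbered 549, which is 8.19% of the T47D list (interval 7.55 to 8.87%), while 2.94% of positions lay in those stretches. Of these peaks 13.3% overlapped an MCF-7 peak (interval 10.6 to 16.4%), against 63.7% of T47D peaks elsewhere (interval 62.5 to 64.9%). In MCF-7, 488 peaks lay there (1.81% of the list), and they were shared at 14.96% against 14.77% elsewhere. This division of the genome was chosen after the data were seen.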

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

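Leaving out peaks near centromere gaps, and leaving the ZNF217 megabase out of band 20q13, were chosen after the data were seen, and the other alternatives were planned. Of the values under alternatives, 32 stayed within the interval of the reported share, within 1.5 times the reported count, or within the quartile range of the reported width, and 21 did not. This tally does not measure robustness. Peak counts in the stronger 50% of each list moved by construction, and random draws kept the MCF-7 share by construction. Bin counts were compared between settings with different numbers of bins, so their shares of the bins tested are given below. With as many MCF-7 as T47D peaks, the shared part of both lists was 32.7% when the strongest MCF-7 peaks were taken. With random ones the T47D share was 14.7%, which follows from the draw. The T47D share was 58.2% with midpoints within 200 bp, 58.4% in the stronger 50% of each list, and 63.7% without peaks near centromere gaps. In the strongest of the 5 classes the share was 31.1% in MCF-7 and 65.4% in T47D when peaks were ranked by width, and 79.3% in T47D without peaks near centromere gaps. Taking the stronger 50% of each list left, by construction, 13510 and 3351 peaks covering 7714 and 1359 kb. Bins above the genome-wide part numbered 48 of 304 at 10 Mb (15.8%), and 41 of 306 (13.4%) with 32 below (10.5%) at matched numbers and a genome-wide part of 50%, against 14.02% above and 11.6% below of 528. At 10 Mb 47 lay below (15.5%), and at 2 Mb 70 of 736 (9.51%) lay on each side. The CCND1 megabase held 27 MCF-7 and 6 T47D peaks in its central 500 kb, and 24 and 4 in the stronger 50% of each list. Apart from the smaller lists and windows, the cause was not tested. No paired analysis was possible because the lists carry no values per sample, and for the same reason no replicate could be left out. The alternatives planned for annotation, motifs and gene lists were not run, for lack of an hg19 reference. Depth is unknown, so an unshared peak is one not called in the other list, which does not show that binding was absent.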

Other observations

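The tests on peaks near centromere gaps, on single megabases rich in T47D-only peaks, on the 500 strongest MCF-7 peaks and on band 20q13 were chosen after the results were seen. Some megabases away from centromere gaps were dense in T47D peaks that MCF-7 did not share. The megabase of chromosome 20 from 52 to 53 Mb, which holds ZNF217, a zinc finger gene amplified in some breast cancers, had 21 T47D and 4 MCF-7 peaks, and none was shared. It lies in band 20q13, which is amplified in MCF-7, and the MCF-7 part of its peaks was 16.0% (interval 4.54 to 36.1%). Of all megabase windows, 99.6% had fewer T47D peaks. The megabase of chromosome 8 that holds TRPS1, a GATA-type transcriptional repressor gene, had 29 T47D and 25 MCF-7 peaks, of which 8 in each list were shared, and 93.7% of windows had fewer MCF-7 peaks, so it was dense in both lists. Both windows were chosen because of their T47D-only peaks, and no peak was assigned to either gene. In MCF-7 the densest megabases were chromosome 16, 85 to 86 Mb, with 61 peaks (17 shared), and chromosome 17, 73 to 74 Mb, with 58 peaks (4 shared).

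Among chromosomes 1 to 22 and X, the MCF-7 part of all peaks was lowest on chromosome 21 at 71.8% (interval 68.3 to 75.1%), and without peaks near centromere gaps it was 81.1% there. On chromosome 19 it was 74.9% (interval 72.2 to 77.5%) and on chromosome 11 it was 75.1% (interval 72.9 to 77.2%), and without those peaks these were 77.1 and 75.8%. Chromosome 19 also had the highest share of MCF-7 peaks with a T47D partner, 21.2%. Its share of T47D peaks with an MCF-7 partner was 63.5%, against 59.6% of the whole T47D list. With overlap nearly 1 to 1, the high MCF-7 share largely restates the low MCF-7 part there.

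Most MCF-7 peaks had no T47D peak. The MCF-7 list was 4.03 times as long and overlap was nearly 1 to 1 (3991 MCF-7 against 3992 T47D peaks). Most MCF-7 peaks therefore had to lack a partner, whatever the cause of the difference in length. Lower sensitivity of the T47D list as the whole cause would leave nearly all of the 500 strongest MCF-7 peaks shared. The limit was set at 90% after the results were seen, and 64.8% were shared (interval 60.4 to 68.99%). Of the 500 strongest T47D peaks, 79.2% were shared, so the limit was missed against the longer MCF-7 list too. Missing it therefore does not decide on sensitivity. Narrower T47D peaks would predict a marked gain on widening. With all peaks widened to 1000 bp, the shared part of MCF-7 peaks was 15.2%, against 14.8% as deposited. That share had limited room to rise, because the T47D list was much shorter. The T47D share, which had more room, was 61.1% after widening and 59.6% as deposited. Lower sensitivity may still account for part or all of the difference, since sharing was lower among peaks of lower score. A difference in ERα binding between the cell lines stays open and was not tested, as there was 1 list per line.

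T47D peaks near centromere gaps overlapped MCF-7 peaks less often than other T47D peaks, and 476 of the 2710 unshared T47D peaks lay there. Reads from repeats are a possible explanation, which would predict tight arrays. The median distance of unshared T47D peaks to the nearest other T47D peak was 3025 bp near the gaps and 12362.5 bp elsewhere, a ratio of 0.245, between the limits of 0.1 and 0.5 set for the test. Part of this follows from the density of T47D peaks there, whose share was 2.79 times the share of positions. Thin MCF-7 calling near the gaps would predict few MCF-7 peaks there, and their share relative to the share of positions was 0.614, which also fell between its limits. Repeats and thin calling cannot be told apart from a difference between the lines with these values, because sequence and mappability were not used here.

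Unshared T47D peaks piled up in single megabases away from the centromere gaps. The leading 5 were chromosome 8, 86 to 87 Mb, with 38 of 40 T47D peaks unshared, the TRPS1 megabase with 21 of 29, the ZNF217 megabase with 21 of 21, and chromosome 3, 174 to 175 Mb and 195 to 196 Mb, with 13 of 23 and 13 of 20. Copy gain in T47D is a hypothesis that would raise shared peaks there in the T47D ranking, and the median T47D percentile minus MCF-7 percentile was 10.0 over 27 shared pairs, against -12.4 for all shared peaks. By megabase it was 41.1 over 2 pairs in chromosome 8, 86 to 87 Mb, -2.98 over 8 in the TRPS1 megabase, and 9.48 over 10 and 10.9 over 7 on chromosome 3, with no shared peak in the ZNF217 megabase. The megabases were chosen for T47D-only peaks and the pairs cluster in them, so this comparison does not decide, and regionally stronger ERα binding in T47D would give the same values. Reads from repeats stay open too: the spacing of unshared peaks relative to elsewhere was 0.204 over all 5 megabases, 0.108 in chromosome 8, 86 to 87 Mb, and 0.280 without it, and such a choice of megabases shortens spacing by itself. The 0.877 of the ZNF217 megabase goes against tight arrays there, and its interval of 0.129 to 1.82 over 21 peaks lay above the limit of 0.1 set for them. The interval also reached below the 0.5 set against them, so the test did not decide.

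Bands 17q23 and 20q13 are amplified in MCF-7, and the hypothesis that copy gain raised the MCF-7 part of peaks was tested in both. The part was 86.2% in 17q23 (94 against 15 peaks, interval 78.3 to 92.1%) and 83.5% in 20q13 (395 against 78 peaks, interval 79.9 to 86.7%). Both intervals included the genome-wide 80.1%, so the test on whole bands did not decide. The 5 Mb bins that overlap the bands differed, but they also hold peaks outside them. The bin at 60 to 65 Mb of chromosome 17 had 112 MCF-7 peaks, more than all of 17q23, taken as 57 to 63 Mb. Its value is therefore not a value of the band. Of the 2 bins that overlap 17q23, chromosome 17, 60 to 65 Mb, lay above (93.3%, interval 87.3 to 97.1%) and the other did not. Of the 5 that overlap 20q13, chromosome 20, 55 to 60 Mb (90.7%, interval 84.3 to 95.1%) and 60 to 65 Mb (91.9%, interval 84.7 to 96.4%) lay above, 2 included the genome-wide part, and 50 to 55 Mb (64.4%, interval 50.9 to 76.4%) lay below. The last contains the ZNF217 megabase, and without that megabase the band had 391 against 57 peaks, a part of 87.3% (interval 83.8 to 90.2%). This removal was chosen after that megabase's low MCF-7 part was seen, so it is no test of copy gain. With the strongest MCF-7 peaks matched to T47D in number, where the genome-wide part is 50%, the parts were 66.7% (interval 51.05 to 80.0%) and 57.6% (interval 50.1 to 64.8%). Both of these intervals lay just above 50%, so the answer depended on which MCF-7 peaks were counted. That second calculation had no prediction written for it.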
